A study of Homo sapiens with 24 samples.

How the data were processed

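Gene expression was measured by RNA sequencing in 24 libraries from 3 human triple-negative breast cancer cell lines of the basal subtype, MDA-MB-157, then MDA-MB-231, then MDA-MB-468. Each line was exposed for 3 h to DMSO, thalidomide at 1000 nM, the BET inhibitor BETi-211 at 1000 nM or the BET degrader BETd-246 at 100 nM. The 12 combinations of line and treatment held 2 libraries each, which the series description calls independent biological replicates. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into TruSeq v2 libraries with random primers, a kit that does not mark the strand. Reads from a gene and an overlapping antisense gene can therefore not be told apart.

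The authors deposited 1 table of 14114 genes with 24 columns of FPKM values, that is, fragments per kilobase of transcript scaled to the mapped fragments of the library. The unit is not named in the table and was inferred from the values, which are not whole numbers and sum to 454289 to 534179 per library. In 745 genes the lowest value above 0 fell with transcript length (Spearman's rho -0.72 across genes, which are not independent), as one fragment is worth less FPKM in a longer gene. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Bowtie 0.12.8 and the genome build GRCh38.p5 were used. The program that computed FPKM, its annotation and the filter behind the 14114 genes are not given in the sources used here. Among the 14114 genes, the lowest value of a gene's highest group mean was 1.219 FPKM, so the genes had been filtered on expression before deposit. All columns were matched to samples by name.

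The size of the step that 1 fragment makes at low values put the depth of a library at 43000000 to 63800000 fragments, an estimate and not a deposited count. Within groups, the correlation of log2 values between the 2 libraries was 0.992 to 0.998 across genes. No counting interval was computed, since the table holds no counts.

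Symbols are those of the table. Of the 14114 identifiers, 13951 were found in GENCODE version 29 on GRCh38, which gave the coordinates and gene types printed here, and 12046 of these were protein-coding. Coordinates are 1-based.

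Values were tested on the scale log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. The model had 1 coefficient for each of the 12 groups, no block, a variance trend on mean expression and no robust step, with 12 residual and 3.32 prior degrees of freedom. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 among the 14114 genes of a contrast. The log2 changes and folds below are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. The planned rule wrote "trend and robust off", which can also be read as no trend, so the fit without a trend was added as an alternative. The plan foresaw quasi-likelihood tests for a count table and this limma test for FPKM, so the count tests were not run. The planned filter of a group mean of at least 1 FPKM removed 0 genes.

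Each compound was compared with the mean of the DMSO and thalidomide coefficients of the same line, because the series description names both as controls. Further contrasts were thalidomide against DMSO, BETd-246 against BETi-211, the differences of the BETd-246 effect between lines, and the average effect of each compound over the 3 lines. All of these were fixed before the data were examined, as were the gene lists, the named genes and the alternatives, unless a statement says otherwise.

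The named genes followed a fixed rule. It took the 5 largest rises and 5 largest falls with BETd-246 per line, 3 and 3 with BETi-211, 2 and 2 for the direct contrast and for thalidomide, among called genes with at least 5 FPKM in the higher group and treated libraries beyond all libraries of the other group. The largest called difference each way was taken for each pair of lines. A fixed set of single genes (BRD2, BRD3, BRDT, CRBN, MYC, MYCN, HEXIM1, MCL1, BCL2, BCL2L1, XIAP, BCL2L11, CDK6, CCND1, CDKN1A, FOSL1, E2F1, E2F2 and EGFR) and up to 4 members of each list, with the smallest adjusted p in the average BETd-246 contrast, were added. BRDT and MYCN are not among the genes of the table. Some results for single genes of the fixed set and the lists are not reported.

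The 29 lists were tested with camera in limma at a preset correlation of 0.01, with adjustment over 168 pairs of a list and a contrast of a compound in a line. Camera with an estimated correlation and fry were the other tests. The list of immune cell markers had 2 measured members, CD14 and CSF1R, and was not tested because 5 were required. Counts of members that rose or fell use the adjustment over all genes, and they are given again adjusted over the list alone where that differs.

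Overlaps between the compounds were set beside 100 simulated pairs of unchanged groups against the same controls, beside the product expected of independent lists, and beside values with the DMSO libraries as control of one compound and the thalidomide libraries as control of the other. For the average effects, 100 splits of the libraries within lines were drawn out of 3375.

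The model was tested on simulated data built on the BETd-246 contrast in MDA-MB-468. Of 200 changed genes among 14114, 99.5% were called, and 8 unchanged genes were called, 3.86% of the calls. The changed genes had higher control levels and log2 changes of at least 0.5 in size, and the noise was independent between genes with the fitted spread. The test therefore does not cover genes at low levels, smaller changes or correlated genes. In an unchanged simulation, camera gave an unadjusted p below 0.05 for 7% of 200 random lists of 20 genes. Simulated genes were independent, so this cannot test the preset correlation.

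The alternatives were quantile normalization, upper-quartile scaling, column-total scaling, pseudocounts of 0.1 and 5, at least 5 FPKM in 2 libraries, each line fitted alone, the replicate number as a block, DMSO or thalidomide alone as control, an adjusted p below 0.01, a fold of at least 2, and each library left out in turn. Added after the data were seen were the fit without a variance trend, median-of-ratios scaling over 13341 genes, protein-coding genes alone (12033 genes, with the 13 mitochondrial mRNAs left out and the libraries rescaled to equal totals of these genes; for the list test the genes were restricted without rescaling), the counts of genes past a fold of 2 and of opposite calls under the alternatives, the medians of the lists and gene classes under each scaling, and the gene types of the calls past a fold of 2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.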

Results

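The transcriptome of 3 triple-negative breast cancer cell lines was profiled after 3 h of exposure to compounds that target BET proteins, a family of bromodomain proteins that bind acetylated chromatin. BETi-211 (1000 nM) is a BET inhibitor, and BETd-246 (100 nM) is a BET degrader. DMSO and thalidomide (1000 nM), a ligand of the ubiquitin ligase receptor cereblon, served as controls. Sets of 3 values are given in the order MDA-MB-157, then MDA-MB-231, then MDA-MB-468. The 12 groups of a line and a treatment held 2 libraries each, 24 in all, and each line had 4 control libraries. The 14114 genes of the table had FPKM sums of 454289 to 534179 per library. The share of the FPKM sum from mitochondrial genes was 7.18% to 8.33% in the control libraries of MDA-MB-468, 8.44% to 8.93% with BETi-211 and 9.55% to 9.74% with BETd-246. In MDA-MB-231 it was 9.79% to 13.99%, 13.4% to 14.28% and 14.9% to 15.1%, and in MDA-MB-157 8.02% to 10.42%, 10.76% to 12.09% and 9.65% to 11.98%, in the same order.

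Thalidomide was compared with DMSO to see how far the controls differed. In MDA-MB-157 the homeobox gene DLX2 and the Notch feedback regulator NRARP rose slightly with thalidomide, by 0.40 ± 0.06 and 0.40 ± 0.07 on the log2 scale (SE, adjusted p = 0.0274 and 0.0436). HAS2, a hyaluronan synthase, and IL7R, the interleukin 7 receptor chain, fell by 0.39 ± 0.05 and by 0.31 ± 0.05 (adjusted p = 0.0047 and 0.0345). With limma, 26 genes were called in MDA-MB-157, 16 higher and 10 lower, 0 of them by a fold of 2. No gene was called in MDA-MB-231 or MDA-MB-468 (count 0 with limma in each), where 766 and 1980 genes had an unadjusted p below 0.05, against 2093 in MDA-MB-157. The calls of DLX2, NRARP, HAS2 and IL7R ended with a pseudocount of 0.1 (adjusted p = 0.398, 0.0966 and 0.0794 for the first 3) and with the line fitted alone. These counts rested on single libraries. In MDA-MB-157 the count was 1026 without DMSO replicate 1, 0 without DMSO replicate 2, 4 without thalidomide replicate 1 and 0 without thalidomide replicate 2. It was 3200 in MDA-MB-231 without thalidomide replicate 2 and 71 in MDA-MB-468 without thalidomide replicate 1.

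The effect of the degrader was measured by comparing BETd-246 with the controls of the same line. The largest falls were in MYC, the proto-oncogene transcription factor, in PLK2, a polo-like kinase, in the ID1 and ID3 inhibitors of DNA binding, in SGK1, a serum- and glucocorticoid-regulated kinase, in DKK1, a secreted Wnt antagonist, and in TGIF1, a homeobox repressor of TGF-beta signalling. PLK2 went from 124.6 ± 10.4 FPKM in the controls (SD, n = 4) to 10.43 ± 0.24 (SD, n = 2) in MDA-MB-231, a fall by 3.45 ± 0.05 on the log2 scale (SE). MYC went from 60.96 ± 2.11 to 5.365 ± 0.477 FPKM in MDA-MB-468, a 9.74-fold fall. TGIF1 was among the 5 largest falls in each line, at 6.36-, 6.45- and 7.13-fold. The others were FAM46A (6.44-fold), KCNE4, a potassium channel subunit (6.07-fold), ID3 (5.43-fold) and SGK1 (5.36-fold) in MDA-MB-157, SGK1 (7.32-fold), CITED2, a CBP and p300 binding protein (6.76-fold), and DKK1 (6.41-fold) in MDA-MB-231, and ID1 (8.05-fold), DKK1 (7.74-fold) and PLK2 (7.56-fold) in MDA-MB-468. The adjusted p of these falls was 3.28e-13 or lower.

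Fewer genes rose strongly with BETd-246, and they were of different kinds. The immediate-early transcription factors FOS and EGR1 rose 10.2- and 9.20-fold in MDA-MB-157 and 11.1- and 21.5-fold in MDA-MB-231, EGR1 from 2.871 ± 0.352 to 82.1 ± 2.82 FPKM in the latter. ARC, another immediate-early gene, rose 9.46-fold in MDA-MB-157. RNU4ATAC, the U4atac small nuclear RNA of the minor spliceosome (chromosome 2, 121530881 to 121531007), rose 8.47-, 11.3- and 11.1-fold in the 3 lines. The U5 small nuclear RNA gene RNU5B-1 (chromosome 15, 65304677 to 65304792) rose 9.84-fold in MDA-MB-231 and 7.86-fold in MDA-MB-468, and RNU5A-1 (chromosome 15, 65296051 to 65296166) 8.82-fold in MDA-MB-468. RP11-386I14.4, an antisense transcript (chromosome 1, 78004346 to 78004554), rose 7.17-fold in MDA-MB-157 and 8.69-fold in MDA-MB-468. AC245407.1, without an entry in the annotation used, rose 9.64-fold in MDA-MB-231, and CTD-3014M21.1, a transcript of unproven status (chromosome 17, 43360041 to 43361361), 7.74-fold in MDA-MB-468. The adjusted p of these rises was 2.51e-08 or lower. Both treated libraries lay above all 4 controls, which the rule for naming these genes required. Small nuclear RNAs have near-identical copies, and the antisense transcript overlaps another strand in libraries without strand, so the values of these single genes are uncertain.

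By limma, 7263 genes were called with BETd-246 in MDA-MB-157, 6788 in MDA-MB-231 and 7602 in MDA-MB-468. The split of higher and lower calls was 2685 and 4578, 2086 and 4702, and 2843 and 4759, that is, 37.0%, 30.7% and 37.4% higher. This split followed the scaling between libraries: 62.0%, 62.1% and 62.4% were higher after quantile normalization, 54.7%, 50.3% and 50.7% after upper-quartile scaling, 15.8%, 9.9% and 17.9% after column-total scaling, and 64.7%, 65.0% and 64.1% after median-of-ratios scaling. The median log2 change of all genes was -0.03, -0.05 and -0.03 in the deposited values, -0.10, -0.12 and -0.10 after column-total scaling and 0.09, 0.08 and 0.09 after median-of-ratios scaling, so small changes have no fixed direction. Among genes changed at least 2-fold, 593, 644 and 862 fell and 36, 58 and 47 rose, 5.7%, 8.3% and 5.2% higher. Few of these rises and most of the falls were in protein-coding genes, 4, 9 and 7 of the rises and 559, 585 and 794 of the falls. With quantile normalization, 10.2%, 19.3% and 11.1% of such calls were higher, with column-total scaling 4.5%, 6.7% and 4.5%. In all 3 lines, 383 genes fell and 31 rose at least 2-fold, and the changes correlated between lines across genes with r = 0.839 to 0.853. Averaged over the lines, 9894 genes were called, 3937 higher and 5957 lower, and 695 of them by a fold of 2.

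**Figure D1:**
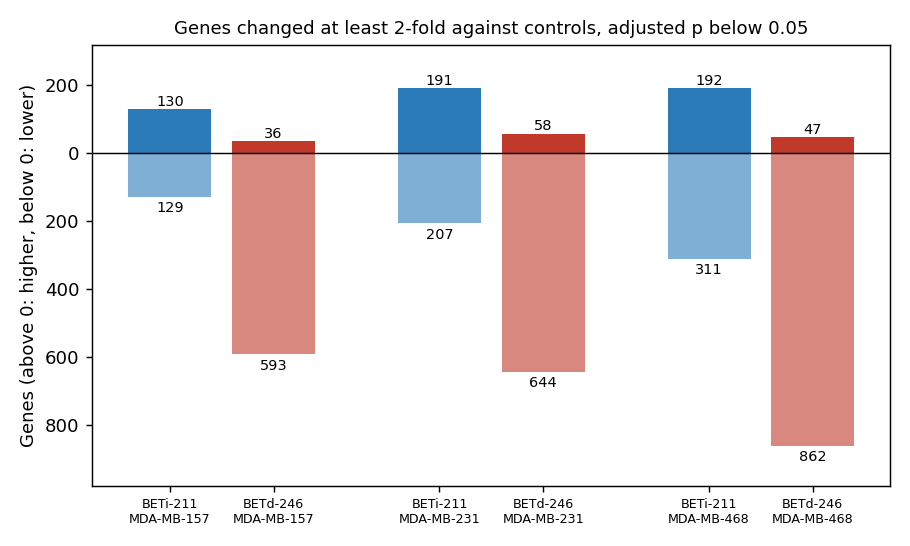
Number of genes with an adjusted p below 0.05 and a change of at least 2-fold against the 4 control libraries of the same line, for BETi-211 (blue) and BETd-246 (red); bars above 0 count higher genes and paler bars below 0 count lower genes. BETd-246 lowered 593, 644 and 862 genes and raised 36, 58 and 47, while BETi-211 lowered 129, 207 and 311 and raised 130, 191 and 192.

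Among the single genes fixed in advance, BETd-246 lowered the BET gene BRD2 by 1.15 ± 0.04, 0.77 ± 0.04 and 1.19 ± 0.04 on the log2 scale (SE). MYC fell by 1.91 ± 0.07, 2.51 ± 0.07 and 3.28 ± 0.07. MCL1, an anti-apoptotic BCL2-family gene, fell by 1.72 ± 0.04, 1.70 ± 0.04 and 1.47 ± 0.04, from 107.3 ± 3.01 to 31.88 ± 0.67 FPKM in MDA-MB-157. HEXIM1, an inhibitor of the elongation factor P-TEFb, fell by 0.97 ± 0.05, 1.26 ± 0.05 and 1.10 ± 0.05. E2F2, a cell cycle transcription factor, fell by 1.05 ± 0.04, 1.12 ± 0.04 and 1.64 ± 0.04, and FOSL1, an AP-1 subunit, by 0.92 ± 0.05 and 0.94 ± 0.05 in MDA-MB-157 and MDA-MB-468 and by more in MDA-MB-231 (adjusted p = 3.4e-11). BCL2L11, the pro-apoptotic gene BIM, fell by 0.78 ± 0.13, 0.55 ± 0.13 and 0.77 ± 0.13, its adjusted p in MDA-MB-231 being 0.00283, but 0.113 after quantile normalization, 0.0717 with the line fitted alone and 0.0536 without BETd-246 replicate 1. BCL2L1, which encodes BCL-XL, fell by 0.28 ± 0.04, 0.28 ± 0.04 and 0.51 ± 0.04, and its call in MDA-MB-231 ended after median-of-ratios scaling. The adjusted p of these falls was 0.00283 or lower. CDKN1A, the CDK inhibitor p21, rose by 0.49 ± 0.06 in MDA-MB-231 (adjusted p = 2.94e-06) and had log2 changes of -0.07 ± 0.06 and 0.07 ± 0.06 in MDA-MB-157 and MDA-MB-468 (adjusted p = 0.369 and 0.31).

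Smaller log2 changes of the remaining fixed genes turned with the scaling. BRD3 was called lower in each line (-0.20, -0.26 and -0.23), CRBN, the cereblon gene, in each line (-0.20, -0.14 and -0.11), XIAP, an inhibitor of apoptosis, in each line (-0.31, -0.23 and -0.33), and BCL2 in MDA-MB-231 and MDA-MB-468 (-0.18 and -0.24, against -0.10 in MDA-MB-157). After quantile normalization the change was above 0 for BRD3 in each line, for CRBN and BCL2 in MDA-MB-231 and MDA-MB-468, and for XIAP in MDA-MB-231. The BRD3 calls also ended with DMSO alone as control (adjusted p = 0.254, 0.0857 and 0.186), and those of CRBN in MDA-MB-157 and MDA-MB-468 with thalidomide alone (adjusted p = 0.0556 and 0.344). CCND1, cyclin D1, was called lower in MDA-MB-468 (-0.12) and CDK6 higher there (0.12), and CCND1 turned after median-of-ratios scaling, while the CDK6 call ended after column-total scaling (adjusted p = 0.652). E2F1 and EGFR, the epidermal growth factor receptor, were not called, with log2 changes of 0.10, 0.08 and 0.04 and of 0.04, -0.06 and -0.08.

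**Figure D2:**
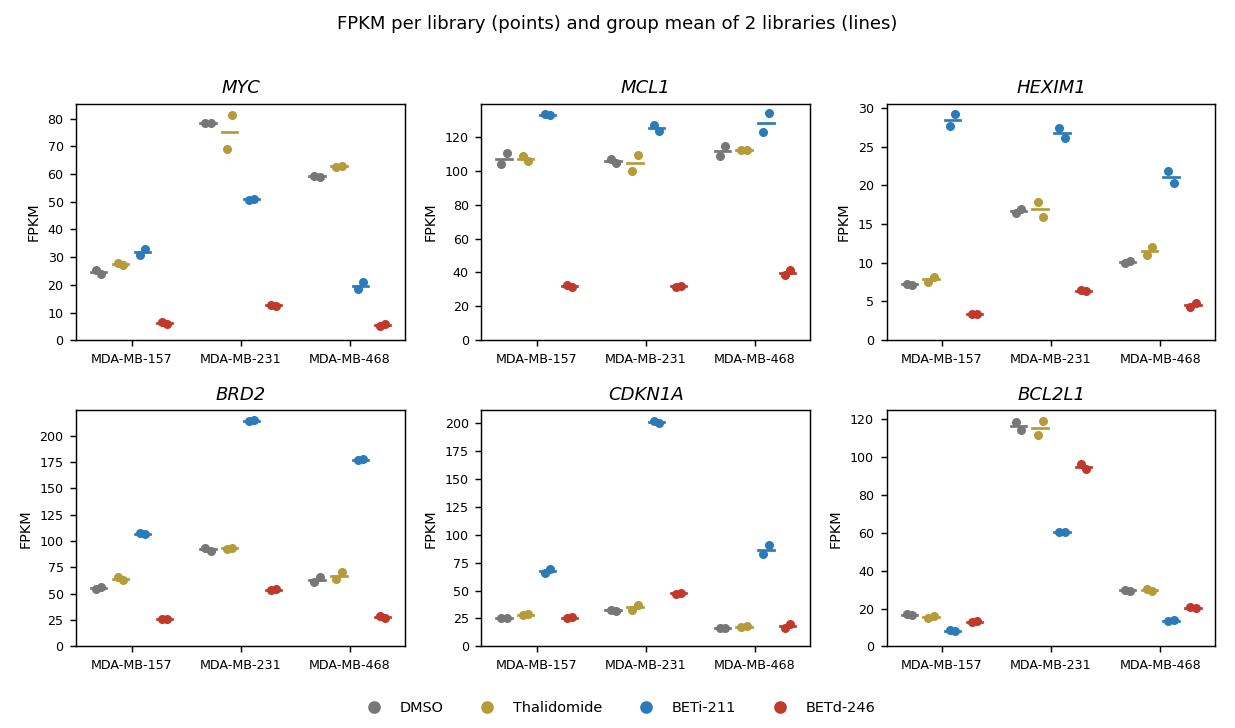
FPKM of 6 genes fixed in advance in each of the 24 libraries, by cell line and treatment; points are libraries and short lines are the means of 2 libraries. MYC, MCL1, HEXIM1 and BRD2 lay below the controls with BETd-246 in each line, while BRD2 and HEXIM1 lay above them with BETi-211.

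Several of the fixed gene lists fell with BETd-246. Of 20 measured genes of the integrated stress and unfolded protein response, 13 fell in each line and 3, 1 and 4 rose (2 adjusted over the list alone in MDA-MB-231), with medians of -1.07, -0.74 and -1.03. They included DDIT4, an inhibitor of mTORC1 (-1.67, -2.56 and -2.31), and CEBPB, a bZIP transcription factor (-1.78, -1.40 and -2.44). Camera gave adjusted p = 0.000231, 0.000702 and 0.000975, and the call was lost with an estimated correlation (adjusted p = 0.338, 0.349 and 0.349). Of 17 measured p53 target genes, 11 fell in each line and 2, 0 and 3 rose, with medians of -0.30, -0.30 and -0.32 (-0.17, -0.01 and -0.28 after quantile normalization), led by PLK2 and the exonuclease gene AEN (-1.42, -1.67 and -1.34). Their camera adjusted p was 0.0132, 0.0164 and 0.0295 (adjusted p = 0.338, 0.338 and 0.349 with an estimated correlation). Of 28 measured immediate-early genes, 19, 17 and 18 fell and 6, 9 and 8 rose, with medians of -0.79, -0.73 and -0.55. Among them the MAP kinase phosphatase DUSP4 (-1.42, -2.37 and -2.06) and IER5 (-1.85, -1.61 and -2.18) fell, opposite to FOS and EGR1. The list was called lower in MDA-MB-157 and MDA-MB-468 (camera adjusted p = 0.000975 and 0.0148) and not in MDA-MB-231 (0.188), and the calls were lost with an estimated correlation (adjusted p = 0.431 and 0.547).

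Genes of survival and of death both fell with BETd-246. Of 9 measured survival genes of the BCL2 family and inhibitors of apoptosis, 6, 8 and 8 fell and 0, 0 and 1 rose, with medians of -0.25, -0.28 and -0.33 that shrank to -0.125, -0.08 and -0.15 after median-of-ratios scaling. BIRC2 and BIRC3, inhibitors of apoptosis that act in NF-kB signalling, fell by 0.70, 0.56 and 0.63 and by 0.25, 1.23 and 0.75. Its camera adjusted p was 0.0298, 0.00628 and 0.0097 (adjusted p = 0.349, 0.338 and 0.338 with an estimated correlation). Of 19 measured pro-apoptotic and death receptor genes, 11, 11 and 14 fell (12, 11 and 15 adjusted over the list alone) and 1, 0 and 2 rose (1, 0 and 3), led by the adaptor gene FADD (-2.01, -1.81 and -2.26). This list was called in MDA-MB-157 and MDA-MB-468 (camera adjusted p = 0.0297 and 0.0109), and with an estimated correlation the adjusted p was 0.431 and 0.373. Of 16 measured P-TEFb and elongation genes, 8, 9 and 9 fell and 1 rose in each line, among them CCNT1, the cyclin of P-TEFb (-1.39, -1.31 and -1.17), and MEPCE, the 7SK capping enzyme (-1.46, -1.76 and -1.60). It was called in MDA-MB-231 (camera adjusted p = 0.0418) and not in MDA-MB-157 or MDA-MB-468 (0.0531 and 0.0604), and with an estimated correlation the adjusted p in MDA-MB-231 was 0.349.

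Further lists were called lower with BETd-246 in 1 line. In MDA-MB-468, 7 of 11 MYC and MAX network genes fell and 0 rose, including the MYC antagonist MXD1 (-1.35), and 12 of 18 NF-kB and cytokine genes fell and 1 rose, including NFKBIE (-1.21). The camera adjusted p was 0.024 and 0.0239 (adjusted p = 0.338 and 0.431 with an estimated correlation). In MDA-MB-157, 17 of 25 S, G2 and M phase genes fell and 2 rose, including the mitotic kinase AURKA (-0.97), and 12 of 23 homologous recombination genes fell and 0 rose, including PALB2 (-1.04), a BRCA2 partner. Their camera adjusted p was 0.023 and 0.0442 (adjusted p = 0.431 for both with an estimated correlation).

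Relative to the rest of each library, ribosomal protein genes rose together with BETd-246, by little. Of 26 measured genes, 25, 26 and 26 rose (26 in each line adjusted over the list alone), with medians of 0.24, 0.25 and 0.27, such as RPL3 (0.21, 0.19 and 0.25), whose calls ended after quantile normalization. For the list, camera gave adjusted p = 2.12e-07, 1.77e-08 and 9.68e-08, lost with an estimated correlation (adjusted p = 0.449, 0.431 and 0.431), and quantile normalization left medians of 0.05, 0.05 and 0.06. Of 22 nuclear genes of the mitochondrial respiratory chain, 18, 20 and 16 rose and 0 fell (20, 20 and 19 rose and 1, 0 and 0 fell adjusted over the list alone), such as COX5A (0.12, 0.16 and 0.25), with camera adjusted p = 0.000181, 2.69e-06 and 7.07e-05 (adjusted p = 0.46, 0.431 and 0.449 with an estimated correlation). The mitochondrial share of the FPKM sum lay above all controls with BETd-246 in MDA-MB-231 and MDA-MB-468 and overlapped them in MDA-MB-157. Among 21 autophagy and lysosome genes, 10, 8 and 10 rose (11 in MDA-MB-468 adjusted over the list alone) and 3, 2 and 3 fell, such as the cathepsin gene CTSD (0.33, 0.19 and 0.33). That list had camera adjusted p = 0.0164, 0.0442 and 0.0295 (adjusted p = 0.46, 0.547 and 0.522 with an estimated correlation), and its median in MDA-MB-231 turned to -0.01 after column-total scaling. FPKM is a share of each library, so the rises of these lists, here and with BETi-211 below, are relative to other RNAs. Absolute amounts were not measured. In MDA-MB-468 the median FPKM of a library was 9.688 to 10.059 in the controls and 7.888 to 7.939 with BETd-246. It was also lower with BETd-246 in the other lines.

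Markers of endothelial cells and fibroblasts were called higher in MDA-MB-157, where 7 of 8 measured genes rose and 1 fell, such as COL3A1 (0.23) and LUM (0.22), with a median of 0.18 and camera adjusted p = 0.0191 (adjusted p = 0.338 with an estimated correlation). In MDA-MB-231 and MDA-MB-468, 0 rose and 2 and 1 fell (1 and 0 adjusted over the list alone), uncalled by camera (adjusted p = 0.775 and 0.474). Of the immune cell markers, CD14 and CSF1R were measured. Lists without a camera call with BETd-246 in any line held strong single changes. Of 21 epithelial and basal genes, 7, 7 and 11 fell and 2, 1 and 9 rose (10 in MDA-MB-468 adjusted over the list alone), and the transcription factor genes KLF5 (-1.29, -1.29 and -1.85) and TFAP2C (-1.66 and -2.06 in MDA-MB-231 and MDA-MB-468) fell in each line. Of 25 TGF-beta and mesenchymal genes, 11, 11 and 9 fell and 7, 3 and 4 rose (8, 3 and 5 adjusted over the list alone), with the inhibitory SMAD7 at -2.07, -1.59 and -1.92. Of 14 G1 cyclin, CDK and E2F genes, 6, 7 and 7 fell and 3, 2 and 3 rose, with the phosphatase CDC25A at -1.51, -1.54 and -1.62, and of 7 CDK inhibitors 4, 3 and 4 fell and 1, 2 and 2 rose, with CDKN1B (p27) at -1.39, -0.62 and -1.10.

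The remaining lists had no camera call with BETd-246 either. Of 22 interferon-stimulated genes, 7, 7 and 6 fell and 7, 3 and 6 rose, with IRF1 lower by 2.02, 2.10 and 2.59. Of 27 YAP and TEAD targets, 9, 13 and 13 fell and 3, 3 and 4 rose (5 in MDA-MB-468 adjusted over the list alone), with the kinase gene NUAK2 at -1.72, -1.88 and -2.02. Of 26 ribosome biogenesis and nucleotide genes, 12, 12 and 11 fell and 3, 2 and 4 rose, with RRS1 at -1.16, -1.19 and -1.29. Of 25 cholesterol genes, 8, 5 and 10 fell (11 in MDA-MB-468 adjusted over the list alone) and 7, 8 and 10 rose, and of 19 heat shock genes 7, 3 and 7 fell (2 in MDA-MB-231 adjusted over the list alone) and 4, 5 and 7 rose. Of 22 histone genes, 10, 5 and 5 fell and 1, 5 and 7 rose (1, 4 and 8 adjusted over the list alone), and of 20 receptor tyrosine kinases 3, 2 and 5 fell and 6, 3 and 2 rose. Of 10 luminal and hormone receptor genes, 1, 2 and 3 fell and 3, 1 and 3 rose, with XBP1 at -1.14, -1.22 and -1.26. Of 8 genes of BET proteins and the cereblon ligase, 3 fell in each line and 3, 0 and 3 rose (4 fell and 3 rose in MDA-MB-231 adjusted over the list alone), and of 6 cereblon neosubstrate genes 3, 4 and 4 fell and 0 rose, with ZFP91 at -0.44, -0.49 and -0.34.

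BETi-211 was compared with the same controls. DKK1 was among the 3 largest falls in each line, 6.12-, 4.93- and 6.38-fold. BMP4, a secreted growth factor of the TGF-beta family, and RASSF9 fell 3.87- and 3.72-fold in MDA-MB-157, HAS2 and the cytokine LIF 5.93- and 5.68-fold in MDA-MB-231, and the forkhead gene FOXI1 and the cAMP phosphodiesterase PDE4B 6.90- and 6.82-fold in MDA-MB-468. FOS rose 5.51-fold and RGS2, a regulator of G-protein signalling, 5.18-fold in MDA-MB-157, where RGS2 went from 4.916 ± 0.368 (SD, n = 4) to 29.57 ± 0.42 FPKM (SD, n = 2). TNFSF9, the 4-1BB ligand, rose 7.35-fold and FAM222A 6.02-fold in MDA-MB-231, and the antisense transcript AP000692.10 rose 7.64-fold in MDA-MB-468. Histone loci were among the largest rises, with the H1 pseudogene HIST1H1PS1 6.13-fold in MDA-MB-157, the H4 gene HIST2H4B 6.07-fold in MDA-MB-231 and 6.18-fold in MDA-MB-468, and the pseudogene RP1-34B20.4 (chromosome 6, 26202156 to 26202654) 6.81-fold in MDA-MB-468. The adjusted p of these changes was 6.05e-08 or lower. HIST2H4B has an identical copy and pseudogenes share reads with their parents, so these values are uncertain.

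With BETi-211, limma called 6471 genes in MDA-MB-157, 7067 in MDA-MB-231 and 7601 in MDA-MB-468, 2107, 2641 and 3013 higher and 4364, 4426 and 4588 lower. The share of higher calls was 32.6%, 37.4% and 39.6%, and 48.8%, 50.5% and 51.1% after quantile normalization, 53.8%, 53.5% and 54.9% after upper-quartile scaling, 23.1%, 25.1% and 26.3% after column-total scaling and 50.5%, 53.6% and 54.4% after median-of-ratios scaling. At least 2-fold, 130, 191 and 192 genes rose and 129, 207 and 311 fell, 50.2%, 48.0% and 38.2% higher. That share was 39.5%, 39.3% and 30.9% with column-total scaling and 62.4%, 56.7% and 49.0% with upper-quartile scaling. In all 3 lines, 59 genes rose and 59 fell at least 2-fold, and the changes correlated between lines with r = 0.737 or higher across genes. Averaged over the lines, 9485 genes were called, 3758 higher and 5727 lower.

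Of the fixed single genes, CDKN1A rose by 1.29 ± 0.06, 2.55 ± 0.06 and 2.27 ± 0.06 on the log2 scale (SE) with BETi-211, from 33.62 ± 2.38 (SD, n = 4) to 200.8 ± 1.21 FPKM (SD, n = 2) in MDA-MB-231. HEXIM1 rose by 1.78 ± 0.05, 0.64 ± 0.05 and 0.90 ± 0.05, BRD2 by 0.83 ± 0.04, 1.20 ± 0.04 and 1.43 ± 0.04, and BCL2L11 by 0.97 ± 0.13, 1.06 ± 0.13 and 0.94 ± 0.13. MCL1 rose by 0.31 ± 0.04, 0.25 ± 0.04 and 0.20 ± 0.04, the last with an adjusted p of 0.00155 that was 0.0728 after quantile normalization and 0.0656 after column-total scaling, and the call also ended without BETi-211 replicate 2. MYC rose in MDA-MB-157 (0.28 ± 0.07, adjusted p = 0.00215) and fell by 0.58 ± 0.07 and by 1.58 ± 0.07 in MDA-MB-231 and MDA-MB-468. E2F2 fell by 1.42, 1.18 and 1.72, FOSL1 by 0.93, 1.54 and 0.78, BCL2L1 by 0.86, 0.93 and 1.07, XIAP by 0.55, 0.27 and 0.51, CCND1 by 0.29, 0.43 and 0.29, and CRBN by 0.30, 0.17 and 0.32. BCL2 was called lower in each line (-0.24, -0.17 and -0.25), CDK6 in MDA-MB-231 and MDA-MB-468 (-0.42 and -0.10), and EGFR there too (-0.22 and -0.29). The calls of EGFR, BCL2 and CRBN in MDA-MB-231 ended after quantile normalization (adjusted p = 0.122, 0.274 and 0.265), and the CDK6 change in MDA-MB-468 turned to 0.07 after quantile normalization. BRD3 was not called (0.14, 0.09 and 0.11), and E2F1 was called in MDA-MB-468 (0.13, adjusted p = 0.0455), a call that ended with thalidomide alone as control (adjusted p = 0.311).

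Stress and signalling lists rose with BETi-211. Of 28 immediate-early genes, 19, 14 and 17 rose and 8, 10 and 7 fell (8 in MDA-MB-468 adjusted over the list alone), with medians of 0.33, 0.28 and 0.36. The list was called in MDA-MB-157 and MDA-MB-468 (camera adjusted p = 0.000557 and 0.0098), not in MDA-MB-231 (0.0529), and was lost with an estimated correlation (adjusted p = 0.431 and 0.524). Of 19 heat shock and chaperone genes, 8, 10 and 12 rose and 1 fell in each line, HSPA1B (an HSP70 gene) by 1.12, 1.60 and 1.68 and the co-chaperone DNAJB1 by 0.59, 1.01 and 1.09. Camera gave adjusted p = 0.0119, 0.000975 and 0.000181 (adjusted p = 0.431, 0.373 and 0.349 with an estimated correlation), and the median in MDA-MB-157 was -0.02 after column-total scaling. Of 20 integrated stress genes, 6, 12 and 13 rose (6, 13 and 13 adjusted over the list alone) and 5, 3 and 5 fell, among them SESN2, a stress-induced inhibitor of mTORC1 (0.96, 1.37 and 1.25). That list was called in MDA-MB-231 and MDA-MB-468 (camera adjusted p = 0.00377 and 0.0177), lost with an estimated correlation (adjusted p = 0.349 and 0.431). Of 25 cholesterol genes, 10, 15 and 13 rose (10, 16 and 13 adjusted over the list alone) and 1, 2 and 3 fell, with INSIG1, a sterol sensor, at 0.67, 1.26 and 1.32. Their camera adjusted p was 0.00377, 0.000333 and 0.0036 (adjusted p = 0.351, 0.349 and 0.351 with an estimated correlation).

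The listed histone genes rose with BETi-211 as a group, least in MDA-MB-157. Of 22 measured, 8, 16 and 18 rose and 3, 0 and 1 fell, with medians of 0.11, 0.49 and 0.45, H2AFX by 0.51, 0.58 and 0.95. Camera gave adjusted p = 0.0191, 5.31e-06 and 4.67e-05 (adjusted p = 0.652, 0.431 and 0.431 with an estimated correlation). A wider set of 70 protein-coding histone genes, taken by symbol after the data were seen, changed less. In it 22, 35 and 44 rose and 11, 1 and 5 fell, with medians of 0.04, 0.18 and 0.24. Of 7 CDK inhibitors, 3, 2 and 5 rose and 3, 2 and 1 fell (2 in MDA-MB-468 adjusted over the list alone), with CDKN2B (p15) at 1.18 in MDA-MB-468, where the list was called (camera adjusted p = 0.00741, and adjusted p = 0.349 with an estimated correlation). Of 21 autophagy and lysosome genes, 6, 10 and 14 rose (15 in MDA-MB-468 adjusted over the list alone) and 3, 1 and 4 fell, with camera adjusted p = 0.0191, 0.00721 and 0.00845 (adjusted p = 0.468, 0.431 and 0.431 with an estimated correlation). TFEB, a transcription factor of lysosomal genes, fell by 0.71, 0.68 and 1.02. Of 26 ribosomal protein genes, 3, 10 and 23 rose (0, 9 and 23 adjusted over the list alone) and 0 fell, with camera adjusted p = 0.00266, 0.000975 and 2.6e-05 (adjusted p = 0.652, 0.625 and 0.524 with an estimated correlation), and the median in MDA-MB-231 turned to -0.03 after quantile normalization. Of 22 respiratory chain genes, 1, 6 and 9 rose (0, 2 and 9 adjusted over the list alone) and 2, 0 and 0 fell, called in MDA-MB-231 and MDA-MB-468 (camera adjusted p = 0.0205 and 0.0129, and adjusted p = 0.655 and 0.632 with an estimated correlation). The mitochondrial share of the FPKM sum was above all controls of the line with BETi-211 in MDA-MB-157 and MDA-MB-468, and 1 of 2 libraries lay above them in MDA-MB-231.

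Cell cycle, repair and survival genes fell with BETi-211. Of 25 S, G2 and M phase genes, 18, 18 and 15 fell (19, 18 and 18 adjusted over the list alone) and 1, 2 and 1 rose (3 in MDA-MB-468 adjusted over the list alone), with AURKA lower by 1.12, 0.97 and 0.93 and the kinesin gene KIF23 by 0.68, 0.69 and 0.67. Camera gave adjusted p = 0.000673, 0.00754 and 0.0177 (adjusted p = 0.349, 0.43 and 0.431 with an estimated correlation). Of 23 homologous recombination and Fanconi genes, 15, 16 and 14 fell and 0 rose, with PALB2 lower by 0.60, 0.50 and 0.76, and with camera adjusted p = 0.00266, 0.00868 and 0.0191 (adjusted p = 0.341, 0.349 and 0.351 with an estimated correlation). Of 9 survival genes, 8, 8 and 7 fell and 1 rose in each line, MCL1, with medians of -0.40, -0.59 and -0.51 and camera adjusted p = 0.00266, 0.00238 and 0.00522 (adjusted p = 0.338 in each line with an estimated correlation). Of 27 YAP and TEAD targets, 10, 13 and 14 fell and 5, 5 and 3 rose, with AJUBA lower by 1.38, 1.29 and 1.36, called in MDA-MB-468 (camera adjusted p = 0.0294, and adjusted p = 0.373 with an estimated correlation). Of 26 ribosome biogenesis genes, 11, 15 and 12 fell (11, 16 and 14 adjusted over the list alone) and 5, 3 and 6 rose (7 in MDA-MB-468 adjusted over the list alone), called in MDA-MB-231 (camera adjusted p = 0.0461, and adjusted p = 0.466 with an estimated correlation), with RRS1 lower by 1.66 there.

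The remaining lists had no camera call with BETi-211. Of 17 p53 targets, 8, 10 and 8 rose (9 in MDA-MB-157 adjusted over the list alone) and 4, 5 and 6 fell (7 in MDA-MB-468), SESN1 by 0.85, 1.01 and 0.52 upward and AEN lower by 0.96, 1.44 and 0.85. Of 18 NF-kB and cytokine genes, 10, 9 and 11 fell and 3, 4 and 3 rose, with LIF at -0.33, -2.51 and -2.13. Of 19 pro-apoptotic genes, 9, 5 and 8 fell and 5, 6 and 5 rose. Of 11 MYC network genes, 3, 4 and 4 fell (5 in MDA-MB-468 adjusted over the list alone) and 4, 5 and 5 rose (6 in MDA-MB-231), MXD1 by 1.04, 1.25 and 0.43. Of 22 interferon-stimulated genes, 10, 8 and 8 fell (11 in MDA-MB-157 adjusted over the list alone) and 4, 7 and 7 rose (8 in MDA-MB-231), of 25 TGF-beta genes 10, 10 and 8 fell and 3, 6 and 6 rose (8 in MDA-MB-231), and of 21 epithelial genes 5, 4 and 11 fell and 5, 5 and 3 rose. Of 14 G1 genes, 5, 7 and 6 fell (7 in MDA-MB-468 adjusted over the list alone) and 3, 3 and 4 rose (4 in MDA-MB-231), and of 16 elongation genes 5, 5 and 3 fell (7 in MDA-MB-231) and 5, 4 and 3 rose (2 in MDA-MB-468). Of 20 receptor tyrosine kinases 6, 8 and 7 fell and 5, 6 and 4 rose, of 10 luminal genes 1, 3 and 4 fell and 3, 2 and 2 rose, of 8 BET and ligase genes 3 fell and 1 rose in each line, of 6 neosubstrate genes 2, 3 and 3 fell and 0 rose, and of 8 endothelial and fibroblast markers 2, 2 and 1 fell and 1, 1 and 0 rose. Over both compounds, 61 of 168 pairs of a list and a contrast were called by camera, 0 with an estimated correlation and 141 by fry. The median, mean and test of a list differed in sign in 37 pairs, 0 of them called by camera. Scaling mattered for the size of these list changes: in 47 of the 61 called pairs the median moved by over 1.5 times under at least 1 scaling, and in 3 it turned. The median of the homologous recombination genes with BETd-246 in MDA-MB-157 was -0.01 after median-of-ratios scaling.

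Comparing the compounds directly, at 100 nM for BETd-246 and 1000 nM for BETi-211, shows where they differed at the doses used. TIPARP, a mono-ADP-ribosyltransferase, and RGS2 were 8.46- and 8.43-fold lower with BETd-246 in MDA-MB-157, the ephrin gene EFNA4 and RGS2 7.70- and 7.65-fold lower in MDA-MB-231, and WDR47 and LFNG, a glycosyltransferase of Notch, 9.44- and 9.14-fold lower in MDA-MB-468. WDR47 was at 3.785 ± 0.119 FPKM with BETd-246 and 44.18 ± 0.10 with BETi-211 there (SD, n = 2 each), against 7.708 ± 0.27 in the controls (SD, n = 4). RP11-386I14.4 was higher with BETd-246 by 2.86, 2.81 and 3.45 on the log2 scale, RNU4ATAC 4.91-fold higher in MDA-MB-157, the ribosomal protein pseudogene RPL7P19 6.73-fold in MDA-MB-231 and RNU5A-1 10.6-fold in MDA-MB-468. The adjusted p of these differences was 9.23e-09 or lower. RPL7P19 (chromosome 5, 138473744 to 138474361) lies beyond the end of EGR1 (138465490 to 138469315) on the same strand. The source of its reads was not tested, so its value is uncertain. Limma called 6559, 5887 and 6114 genes between the compounds. The split was 3415, 2509 and 2843 higher with BETd-246 and 3144, 3378 and 3271 lower, 52.1%, 42.6% and 46.5% higher, and it was 64.7%, 61.6% and 64.7% after quantile normalization and 67.5%, 65.6% and 66.0% after median-of-ratios scaling. At least 2-fold, 603, 635 and 699 were lower with BETd-246 and 21, 39 and 37 higher, and 2, 7 and 2 of the higher genes were protein-coding.

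Among the fixed genes, HEXIM1 was lower with BETd-246 than with BETi-211 by -2.76 ± 0.06 and -1.90 ± 0.06 in MDA-MB-157 and MDA-MB-231 (log2, SE) and with a 95% interval of -2.13 to -1.87 in MDA-MB-468, BRD2 by -1.98, -1.97 and -2.62, MCL1 by -2.03, -1.95 and -1.67, MYC by -2.19, -1.93 and -1.70, CDKN1A by -1.35, -2.06 and -2.20, and BCL2L11 by -1.75, -1.61 and -1.72. BCL2L1 was higher with BETd-246 by 0.59, 0.65 and 0.56, CCND1 by 0.29, 0.38 and 0.18 and CDK6 by 0.12, 0.39 and 0.21. Differences that were not called had these 95% intervals on the log2 scale: E2F1 from -0.01 to 0.25, -0.17 to 0.09 and -0.23 to 0.03, EGFR from -0.16 to 0.20, -0.02 to 0.33 and 0.03 to 0.38, E2F2 from -0.03 to 0.16 in MDA-MB-231 and -0.02 to 0.17 in MDA-MB-468, and FOSL1 from -0.12 to 0.15 in MDA-MB-157 and -0.30 to -0.03 in MDA-MB-468. For BCL2 they were 0.01 to 0.28, -0.15 to 0.12 and -0.13 to 0.14, for CRBN -0.01 to 0.20 in MDA-MB-157 and -0.08 to 0.13 in MDA-MB-231, and for XIAP -0.05 to 0.13 in MDA-MB-231. These intervals are not adjusted for the number of genes. BRD3 was lower with BETd-246 by -0.34, -0.35 and -0.34, and after quantile normalization the calls in MDA-MB-231 and MDA-MB-468 ended (adjusted p = 0.193 and 0.212).

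Shared calls were counted against the same controls. Both compounds lowered 2759, 2936 and 3173 genes and raised 629, 826 and 1346, where independent lists would share 1416, 1474 and 1547 and 401, 390 and 607. These shared calls were not recounted under other scalings, on which the split of higher and lower calls of each compound depended. BRD2, HEXIM1, MCL1 and BCL2L11 were among the genes that BETd-246 lowered and BETi-211 raised, 683, 667 and 668 in the 3 lines and 271 in all 3. After quantile normalization the numbers by line were 651, 540 and 587. The opposite way went 117, 61 and 94 genes, numbers not compared by line under other scalings. Opposite calls numbered 800, 728 and 762 in all, against 1514, 1534 and 1940 expected of independent lists. That expectation pools both directions. An excess of genes lower with BETd-246 and higher with BETi-211 within a line was therefore not shown. Across genes the changes of the compounds correlated with r = 0.360, 0.449 and 0.467 (simulated 0.336, 0.334 and 0.337), with a covariance of 0.0468, 0.0697 and 0.0879 (simulated 0.00237, 0.00235 and 0.00237). With DMSO as control of BETd-246 and thalidomide as control of BETi-211, both lowered 2532, 2605 and 2899 genes and raised 350, 554 and 842. In that setting r was 0.353, 0.440 and 0.452. The other way round, both lowered 2336, 2556 and 2859 genes and raised 470, 538 and 1007, and r was 0.292, 0.401 and 0.436. The shared rises were thus fewer with separate controls in each line.

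**Figure D3:**
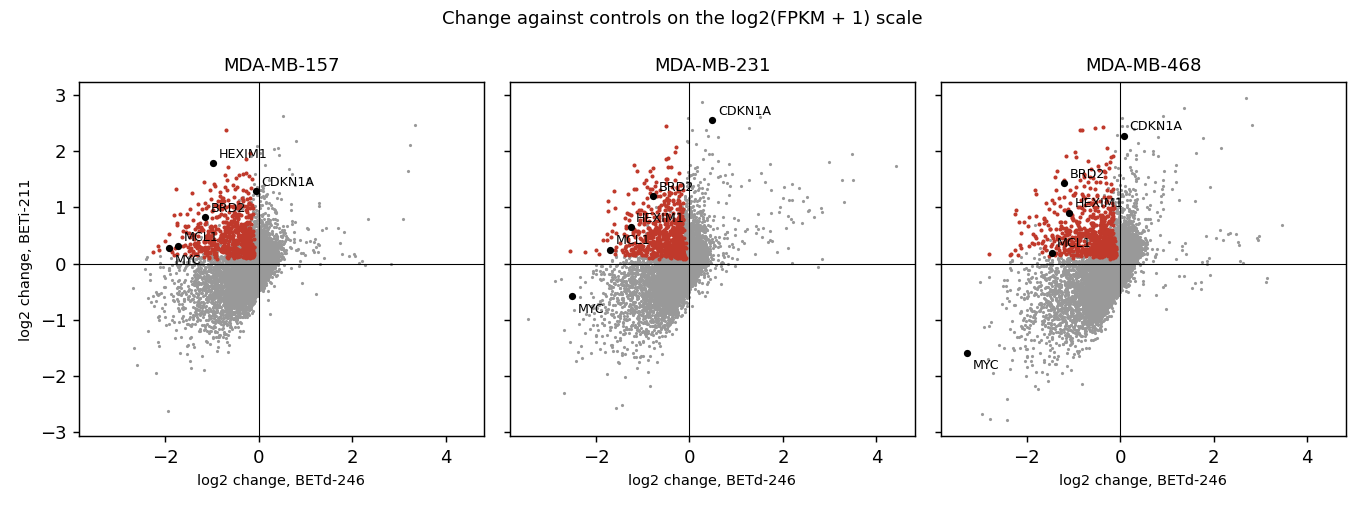
Change of each gene with BETd-246 (x axis) and BETi-211 (y axis) against the controls of the same line, on the log2(FPKM + 1) scale; red points are the 683, 667 and 668 genes called lower with BETd-246 and higher with BETi-211, and black points mark 5 named genes. HEXIM1, BRD2 and MCL1 lie among the red points in each line, while MYC lies below 0 on both axes in MDA-MB-231 and MDA-MB-468.

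The effect of BETd-246 was compared between lines by interaction contrasts. KCNE4 fell more in MDA-MB-157 than in MDA-MB-231 (difference -2.58 ± 0.06 on the log2 scale, SE), where its level was 46.67 ± 2.60 against 0.119 ± 0.035 FPKM in the controls (SD, n = 4). SNAI1, a repressor of epithelial genes, fell in MDA-MB-157 and rose from 0.4551 ± 0.109 to 1.659 ± 0.37 FPKM in MDA-MB-468 (difference -2.76 ± 0.15), and its relative SNAI2 fell in MDA-MB-231 while it was near 0 FPKM in MDA-MB-468 (difference -2.36 ± 0.05). FOXI1, near 0 FPKM in MDA-MB-157, fell in MDA-MB-468 (difference 2.45 ± 0.07), and TRIB1, a pseudokinase, was higher in MDA-MB-231 and lower in MDA-MB-468 (difference 2.65 ± 0.11). SNORD32A, a small nucleolar RNA, differed by 1.63 ± 0.37 between MDA-MB-157 and MDA-MB-231 (adjusted p = 0.00822), a call that ended without BETd-246 replicate 1 of MDA-MB-157, and the adjusted p of the other differences was 2.52e-09 or lower. MYC fell least in MDA-MB-157, with differences of 0.60 ± 0.09 to MDA-MB-231 and 1.37 ± 0.09 to MDA-MB-468. Limma called 1587 genes between MDA-MB-157 and MDA-MB-231, 1847 between MDA-MB-157 and MDA-MB-468 and 1873 between MDA-MB-231 and MDA-MB-468. Without thalidomide replicate 2 of MDA-MB-231 the counts involving that line were 3119 and 3258.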

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

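The interaction tests below were planned, and no technical explanation was weighed for them. The counts of genes whose BETd-246 effect differed between lines drew attention because the difference itself passed limma's test: 1587 between MDA-MB-157 and MDA-MB-231, 1847 between MDA-MB-157 and MDA-MB-468 and 1873 between MDA-MB-231 and MDA-MB-468. Of the 19 genes named for the largest BETd-246 changes, 15 differed between at least 1 pair of lines. They were picked as the largest changes within single lines, which favours such differences, and the share among all genes was not counted.

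Among the fixed single genes, differences of the BETd-246 effect are given as the log2 effect in the line named earlier minus that in the line named later. MYC differed by 0.60 (MDA-MB-157 and MDA-MB-231), 1.37 (MDA-MB-157 and MDA-MB-468) and 0.77 (MDA-MB-231 and MDA-MB-468). BRD2 differed by -0.38 between MDA-MB-157 and MDA-MB-231 and by 0.42 between MDA-MB-231 and MDA-MB-468. CDKN1A differed by -0.56 and 0.42 between the same pairs. HEXIM1 differed by 0.29 between MDA-MB-157 and MDA-MB-231. Between MDA-MB-157 and MDA-MB-468, and between MDA-MB-231 and MDA-MB-468, MCL1 differed by -0.25 and -0.23, BCL2L1 by 0.24 and 0.23, and E2F2 by 0.59 and 0.52.

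The largest differences each way were SNORD32A (1.63) and KCNE4 (-2.58) between MDA-MB-157 and MDA-MB-231, FOXI1 (2.45) and SNAI1 (-2.76) between MDA-MB-157 and MDA-MB-468, and TRIB1 (2.65) and SNAI2 (-2.36) between MDA-MB-231 and MDA-MB-468. KCNE4, FOXI1 and SNAI2 each lay near 0 FPKM in 1 line of the pair, where no fall can be measured.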

How the results depend on the processing

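Chosen after the data were seen were the fit without a variance trend, median-of-ratios scaling, protein-coding genes alone, the counts past a fold of 2 and of opposite calls under the alternatives, and the list medians under each scaling; the other alternatives were planned. The planned count tests and the fit on counts with precision weights were not run, as the table holds FPKM, and the setting without a filter was void, since the filter removed 0 genes. Where a library was left out, the lone library of its group was assumed to vary like the other groups. The depth per library is an estimate, so counting error could not be separated from biological spread. The counts of calls for each compound, alone and averaged, and between the compounds stayed within 1.5 times of the reported ones under the alternatives other than a fold of 2. The fit without a variance trend also moved no count by that much, and it left 911 single gene values on their side of the threshold, with 1 call gained and 4 lost. Whether the replicate numbers pair the samples stayed open: deviations of same-numbered libraries correlated across genes from -0.06 to 0.30 in MDA-MB-468, from -0.22 to 0.27 in MDA-MB-157 and from -0.32 to 0.23 in MDA-MB-231. With the replicate block, thalidomide called 5 genes in MDA-MB-157, 60 list pairs were called, and no other count moved over 1.5 times.

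Requiring a fold of 2 left 629, 702 and 909 genes for BETd-246 in MDA-MB-157, then MDA-MB-231, then MDA-MB-468, 259, 398 and 503 for BETi-211, 624, 674 and 736 between the compounds, 101, 114 and 134 between lines, 695 and 269 for the averages of BETd-246 and BETi-211, and 0 for thalidomide in MDA-MB-157. At an adjusted p below 0.01, the counts between lines were 849, 1143 and 1157, and thalidomide called 3. Both follow from the stricter limits. Thalidomide in MDA-MB-157 called 209 after quantile normalization, 49 after upper-quartile and 17 after column-total scaling, 7 and 163 with pseudocounts of 0.1 and 5, 112 among protein-coding genes after rescaling and 0 with the line alone. It called 1 in MDA-MB-231 with the line alone, and 1 and 22 in MDA-MB-468 with pseudocounts of 0.1 and 5. Between MDA-MB-157 and MDA-MB-231, 2525 genes were called after quantile normalization. The cause was not tested for these.

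Past a fold of 2, a pseudocount of 0.1 gave 1030 and 1209 genes for BETd-246 in MDA-MB-157 and MDA-MB-231, 506, 775 and 878 for BETi-211, and 980, 1171 and 1109 between the compounds, as it shrinks low genes less. A pseudocount of 5 gave 170, 153 and 278, 53, 116 and 147, and 197, 189 and 274. Quantile normalization gave 383 and 566 for BETd-246 in MDA-MB-231 and MDA-MB-468. With protein-coding genes alone and rescaled without mitochondrial mRNAs, rises past a fold of 2 numbered 4, 9 and 7 with BETd-246 in place of 36, 58 and 47, and 2, 8 and 2 between the compounds in place of 21, 39 and 37. This setting changes genes and scaling together; without rescaling, 4, 9 and 7 and 2, 7 and 2 of the reported rises were protein-coding. Gene list pairs numbered 0 with an estimated correlation and 141 with fry (57 of the 61 among them), against 55 to 66 elsewhere. The medians of 47 of these 61 moved by over 1.5 times under a scaling, and 3 turned.

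After quantile normalization the log2 change with BETd-246 turned to 0.013, 0.048 and 0.10 for BRD3 in the 3 lines, to 0.042 and 0.057 for CRBN and 0.106 and 0.001 for BCL2 in MDA-MB-231 and MDA-MB-468, and in MDA-MB-231 to 0.039 for XIAP, 0.025 for PLEKHM1 and 0.033 for KDR. BCL2 between the compounds turned to 0.18 in MDA-MB-231. With BETi-211, CDK6 turned to 0.065 in MDA-MB-468, RPLP2 to -0.11, RPL7A to -0.10 and ATP5B to -0.004 in MDA-MB-231, and COL3A1 to -0.093 in MDA-MB-157. After median-of-ratios scaling, BETd-246 changes turned to 0.045 (CRBN), 0.16 (CDK6), 0.14 (CCND1) and 0.033 (H2AFX) in MDA-MB-231 and to 0.067 (CRBN), 0.068 (CCND1) and 0.002 (PLK1) in MDA-MB-468. These are small changes near the shift of all genes, and the cause was not tested further.

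Leaving out single libraries, thalidomide called 0 to 1026 genes in MDA-MB-157, 0 to 3200 in MDA-MB-231 and 0 to 71 in MDA-MB-468. The counts between lines ranged from 999 to 3119 (MDA-MB-157 and MDA-MB-231) and from 1282 to 3258 (MDA-MB-231 and MDA-MB-468). Of the single gene values so recomputed, 5076 kept their side of the threshold, 36 gained a call and 172 lost one, and none changed direction after being called.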

Other observations

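The tests of small nuclear RNAs, zinc finger genes and opposite calls below were chosen after the results were seen, out of a look at gene type, exon number, gene span, level, zinc finger names and mitochondrial genes; the splits of the libraries were planned. By median change, small nuclear RNAs were the class that rose most with BETd-246 among the RNA classes compared. Of 33 measured, 17, 25 and 22 rose and 0, 1 and 2 fell in the 3 lines, with medians of 0.81, 1.54 and 1.19 on the log2 scale and medians above 0.70 under each scaling. The summed level of the U5 family changed by 1.85, 2.32 and 2.23. That of U4 and U6 changed by only 0.26, 0.83 and 0.47, without separation from the controls in MDA-MB-157. The U2 entries of the table, RNU2-63P, RNU2-27P and RNU2-24P, have pseudogene symbols, and their sum changed by 1.06, 2.05 and 1.55. Among them RNU2-63P alone was called higher. Of the minor spliceosome RNAs, RNU4ATAC (U4atac) changed by 3.08, 3.50 and 3.47, and RNU6ATAC (U6atac) by 0.26, 0.97 and 0.40, called in MDA-MB-231 alone. Small nucleolar RNAs, which guide RNA modification, did not rise with them: of 164, most were not called, 34, 39 and 47 fell and 4, 5 and 4 rose, with medians of -0.22, -0.19 and -0.34 (-0.06, -0.002 and -0.11 after quantile normalization). With BETi-211 the small nuclear RNAs had medians of 0.14, 0.65 and 0.02, the last being -0.04 after column-total scaling. Of 13 mitochondrial mRNAs, 9, 6 and 11 rose and 0 fell with BETd-246 (medians 0.50, 0.36 and 0.48), and 9, 2 and 2 rose with BETi-211. These are changes in the share of a library, and absolute amounts were not measured.

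Zinc finger genes with ZNF symbols fell with BETd-246 in large numbers. Of 434, 371, 384 and 380 fell and 3, 0 and 6 rose, with medians of -0.68, -0.71 and -0.77 (-0.51, -0.43 and -0.46 after quantile normalization), and the medians with BETi-211 were -0.18, -0.18 and -0.26. Protein-coding genes of 1 exon without histones and ZNF genes fell too with BETd-246 (69, 71 and 72 of 87, medians -0.60, -0.59 and -0.75), as did those of 2 exons (129, 129 and 138 of 183), while 7005 genes of 6 or more exons had medians of -0.001, -0.01 and 0.01, which took either sign under other scalings. The exon classes were limited to genes with a mean control level of at least 5 FPKM, and the ZNF genes were not.

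For the small nuclear RNAs, a gain of all short RNAs in the treated libraries would raise other non-coding RNAs of 100 to 350 nucleotides as much. Both groups were limited to genes of that length with a mean control level of at least 1 FPKM. The median over the lines was -0.13 for the other RNAs (175 genes) and 0.99 for 32 small nuclear RNAs. The difference was 1.117 (permutation p = 0.0001, the smallest the permutations can give). The permutation took genes as independent, but near-identical copies can share reads, so this p overstates the evidence. Reads moved between near-identical copies of the table would leave the summed family level in place, yet the lowest change of the U1 or U5 sum in a line was 1.061. The sums cover only the copies in the deposited table. Reads gained from copies outside it can therefore not be excluded. That these RNAs accumulate after BET degradation may be a hypothesis to follow up; altered 3' ends or processing, which FPKM cannot show, stay open.

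For the zinc finger genes, their low level and their few exons and transcript length were tested with 10000 random lists. Lists matched on control level had a median change of -0.07 and a lowest median of -0.133, against -0.727 for the 434 genes. Lists matched on exon number, transcript length and level had a median of -0.146 and a lowest of -0.219, against -0.728 for 431 genes. A short half-life of these mRNAs may be a candidate explanation, and no half-lives were measured here.

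The 271 genes lower with BETd-246 and higher with BETi-211 in all 3 lines were set against scaling. Their number was 238 after quantile normalization, the lowest of the 4 scalings, with 178 genes in common, and 254 to 304 otherwise, while genes of the reverse pattern went from 5 to 35 after quantile normalization and 68 after median-of-ratios scaling. With separate controls for the compounds, the DMSO libraries for one and the thalidomide libraries for the other, the number was 227 and 254. Partial inhibition against loss of the proteins may account for such genes, but each compound was used at 1 dose, so dose and mode of action were not separated. Opposite calls of both directions together were fewer in each line than expected of independent lists. An excess of such genes within a line was thus not shown.

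For the average effects, the real split of the libraries called 9894 genes with BETd-246 and 9485 with BETi-211, and the highest of the other splits drawn called 7412 and 7626. In each case 1 of 100 splits out of 3375, the real one, gave as many, the lowest number the draw can give. The median of the other splits was 20 and 180. Every split but the real one puts treated libraries among the controls in at least 1 line, which lowers the calls of changed genes. The outcome was thus largely set by the design and adds little to the tests of the effects. Other splits can keep part of the real grouping, and how much each kept was not compared with its count.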
